A study of Mus musculus with 6 samples.

How the data were processed

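Polyadenylated RNA was sequenced from the aortas of C57BL/6 mice in 6 libraries, 2 in each of 3 groups. The control group (Ctrl) was wild type and 2 months old. The ApoE group lacked apolipoprotein E, a ligand that clears lipoprotein particles, and had been kept on chow to an age of 16 months, when its plaques were calcified. The CKD group underwent a staged removal of kidney tissue from 8 weeks of age, with 1 week of recovery between operations, and then received a diet with 2% phosphate and water with 0.45% NaCl for 4 weeks, which calcifies the media. The age label of the CKD libraries reads 16 months, which conflicts with that protocol, so their age is uncertain. Age and genotype differ together between ApoE and Ctrl. The labels do not say whether the libraries came from separate animals, or from pools, while the extraction protocol mentions pools of 4 samples for miRNA sequencing. The SDs and p-values then measure only the spread between these libraries, which may be technical.

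The deposited values were taken as FPKM (reads per kilobase of exon, scaled to the depth of each library) from the values themselves, since no header or label names the unit. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0 and TopHat2 are named with build GRCm38; the role of each, the counting tool and the annotation are not given in the sources used here. Each file held 27815 gene identifiers, and none was at 0 in all 6 libraries. In 5 files the identifiers and the values were stacked in 1 column, and in 1 file they stood in 2 columns. Symbols were matched for 27695 identifiers, and summed exon lengths from GENCODE M21 for 27730. Multiplying a value by exon length gave whole multiples of 1 read, within 0.05, for 89.5% to 89.9% of values. By that scale the libraries held 14.44 to 16.64 M reads, and 1 read in a gene with 2 kb of exon was worth 0.0300 to 0.0346 FPKM. The library kit did not mark strand, so reads of overlapping and antisense genes cannot be told apart. Among the genes named, Spp1, Mmp12, Adam8, Casq1, Haus8, Smtn, Des, Mfap4, Acp5, Cxcl16, Igtp, Slc20a2, Wdfy1, Bcam, Nectin2, Cdkn1a, Myh6, Myoc, Fgfr1, Gbp2, Cd74, Cd22, Cox5a and Plin4 overlap another annotated gene, and their values are uncertain to that extent.

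Values were analysed as log2(FPKM + 1), for the 14074 genes with at least 1 FPKM in at least 2 libraries. Fold changes are on that scale, which understates the change of low genes. All 6 libraries entered a single limma model of group means (limma 3.58.1 in R 4.3.3, with a variance trend and robust spread), and each pair of groups was a contrast. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The design fixed before the data were examined had assumed read counts and named a count model for them. FPKM values do not suit a count model, so the limma test written there for normalized values was used. Gene lists were tested with limma's fry on the same log2 values in place of voom values. The 38 lists covered aortic cell types, calcification, matrix, inflammation, lipid handling, ageing, neighbouring tissues, the clock and tissue handling, and were fixed before the data were examined. Fry tests whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Camera, which does compare them, was run with a preset inter-gene correlation of 0.01 and with an estimated one.

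The genes named were set by a rule fixed before the data were examined. For each comparison they are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 FPKM, a symbol that is not a Gm, Rik, immunoglobulin or T cell receptor name, and libraries that do not overlap between groups. Up to 4 called members with the smallest adjusted p were taken from each list described, or the 1 or 2 most abundant members where none was called. Apoe and a set of check genes were added, and for the overlap of comparisons the 5 genes with the largest changes one way and the 5 with the largest difference the other way. Some genes that the rule selects are not reported here.

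The fit was tested on simulated data of the 14074 genes with 200 genes changed. At a fold of 2 it called 38% of them for ApoE versus Ctrl, 56% for CKD versus Ctrl and 60% for ApoE versus CKD, and at a fold of 4 it called 94%, 93% and 95%. In the same runs it also called 14, 11 and 12 unchanged genes. Genes were drawn independently, and changes were planted only in genes of at least 5 FPKM in Ctrl. Blocks of genes that vary together are therefore absent from these error rates. In 100 draws of unchanged groups the median number of false genes was 0 in each comparison, with at most 6, 8 and 5, and a false list appeared in 7%, 8% and 8% of draws. Libraries were compared by a chi-square over recovered reads, and libraries of one group differed by 19.5 (Ctrl), 38.5 (ApoE) and 75.0 (CKD) times the degrees of freedom, more than the counting noise between copies of the same library. Technical replicates can exceed that noise too, so this does not show separate animals, and each library counted as 1 replicate as labelled. By the same measure CKD 2 and Ctrl 2 differed by 61.1, less than CKD 1 and CKD 2, although r of log2 FPKM was 0.952 for CKD 2 and Ctrl 2 and 0.966 for CKD 1 and CKD 2.

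Alternatives covered scaling, filtering, the pseudocount, the spread estimate, the libraries in the fit, the replicate number as a block, a fold-change minimum and each library left out in turn. The simulation of shared controls was corrected after its first result was seen. A fit of voom on recovered whole reads and a fit with adipocyte level as a covariate were chosen after seeing the data. Adipocyte level was the mean log2(FPKM + 1) of the tested white adipocyte genes in each library. In that fit the mean fold change of the white adipocyte list is therefore fixed by construction. The level differed between groups, with Adipoq at 25.3 and 70.1 FPKM in Ctrl, 256 and 248 in ApoE and 681 and 200 in CKD. Part of any difference from Ctrl is thus removed with it. Calls lost with it therefore cannot tell fat from an effect of group. Figures were drawn with matplotlib 3.10.9.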

Results

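The aorta transcriptome was compared between 2 models of vascular calcification and young wild-type mice. Each of the 3 groups had 2 libraries of 14.44 to 16.64 M reads. Values are FPKM, given as mean ± SD of the 2 libraries, and fold changes are log2 of FPKM + 1 with limma's standard error (SE). Reads from mitochondrial genes made up 3.36% and 4.49% of the Ctrl libraries, 10.40% and 11.82% of the ApoE libraries and 10.70% and 6.12% of the CKD libraries.

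Apoe (ENSMUSG00000002985; GRCm38 chromosome 7, 19696109 to 19699188), the targeted gene, stood at 756 and 627 FPKM in the Ctrl libraries and at 13.2 and 11.4 in the ApoE libraries. In the CKD libraries it stood at 1410 and 1447. Y-linked transcripts were present in all 6 libraries, with Ddx3y between 13.6 and 35.0 FPKM, and Xist, the X-inactivation transcript, did not exceed 0.048. Eif2s3y, Kdm5d and Uty were likewise present, at 13.7 to 26.0, 1.40 to 2.24 and 1.57 to 2.13 FPKM. Of the genes fixed as substrain checks, Nnt did not exceed 0.084 FPKM in any library. Wdfy1 was lower in ApoE (3.86 ± 0.440) than in Ctrl (14.2 ± 0.663, log2 fold change -1.65, limma adjusted p = 0.000426). It was also lower than in CKD (14.65 ± 0.472, log2 fold change -1.69, limma adjusted p = 0.000774).

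The first comparison asked how the aorta with calcified plaques differed from the young wild-type aorta. Macrophage genes rose and smooth muscle genes fell. Spp1 (osteopontin, a secreted phosphoprotein of bone and of activated macrophages; chromosome 5, 104435118 to 104441050) stood at 0.518 ± 0.0616 FPKM in Ctrl and 2880.4 ± 323 in ApoE, a log2 fold change of 10.89 (SE 0.41, adjusted p = 0.000172). The other largest rises were Cd5l, Mmp12, Atp6v0d2, Gpnmb, Lgals3, Mpeg1 and Ctss, with log2 fold changes from 10.06 for Cd5l to 5.80 for Ctss. Among the largest falls were Mir143 (-6.53), Mir145a (-6.10), Carmn (-5.89), Apoe (-5.70), Sost (-5.35), Npnt (-4.93) and Tcap (-4.76). Mir143 (chromosome 18, 61649196 to 61649258) and Mir145a (61647825 to 61647894) are annotated precursors on the same strand as the lincRNA Carmn, which spans 61649625 to 61665537. Their values count reads over the precursors in polyadenylated RNA, not mature miRNAs.

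**Figure D1:**
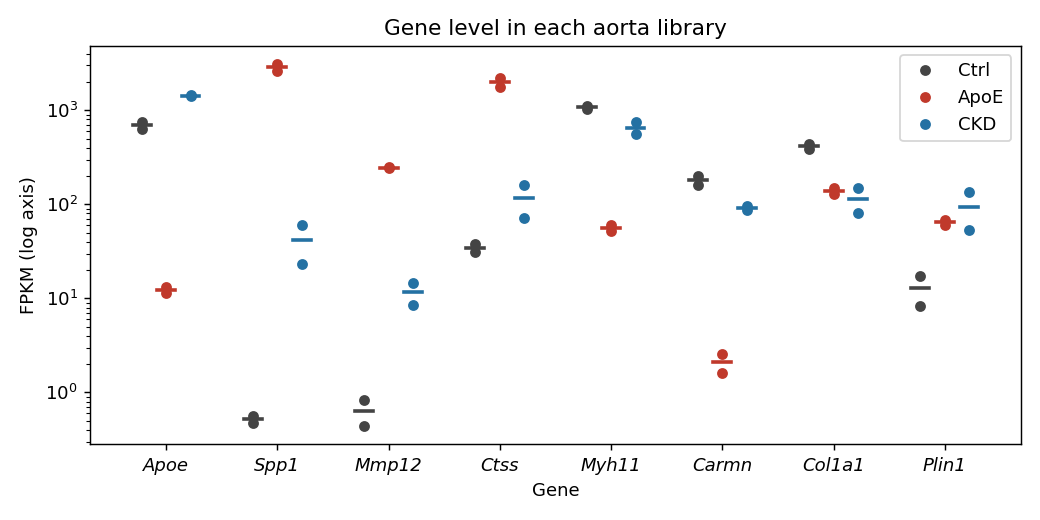
FPKM (log axis) of 8 genes in each library; points are libraries, 2 per group, and bars are group means. Myh11 averaged 1081 FPKM in Ctrl and 55.8 in ApoE and stood at 554 and 755 in the CKD libraries. Mmp12 averaged 0.630 in Ctrl, 246 in ApoE and 11.6 in CKD.

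All 21 tested genes of the contractile smooth muscle list fell in ApoE, with a median log2 fold change of -3.27 (fry adjusted p = 0.00682). The camera adjusted p was 0.598 with an estimated correlation and 2.5e-11 with the preset one. Myh11, smooth muscle myosin, changed by -4.25 (SE 0.22), Synpo2 by -3.69 (SE 0.16), Smtn by -3.50 (SE 0.17) and Tpm2 by -3.38 (SE 0.20). Of the 28 elastin and collagen matrix genes, 19 fell and 2 rose, with a median of -1.32, and the list missed the threshold (fry adjusted p = 0.0540). It passed under upper-quartile scaling (0.0439) and without CKD 1 or CKD 2 (0.0490). Without Ctrl 1, Ctrl 2, ApoE 1 or ApoE 2 its adjusted p was 0.121 to 0.252 (11 genes lower without Ctrl 1 and 12 without ApoE 2), and with adipocyte level as a covariate 6 genes fell and the median was -0.67 (adjusted p = 0.592). Mfap4, a microfibril protein, changed by -3.42, Col6a2 by -2.50, Col6a1 by -2.24 and Vcan by -2.16. Of 16 fibroblast genes, 9 fell and none rose (fry adjusted p = 0.127), among them Mfap5 at -2.13. That count was lower without Ctrl 1, Ctrl 2 or ApoE 2. Adjusted over the list alone, 21 contractile genes, 20 matrix genes and 9 fibroblast genes fell.

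Of 26 macrophage and foam cell genes, 23 rose and none fell, with a median of 3.82 (fry adjusted p = 0.00521). With an estimated correlation camera gave an adjusted p of 0.598 for this list and for each of the osteoclast-like, protease and inflammatory lists, which fry called too. That was its lowest value for any list in this comparison, so it does not separate them. With the preset correlation camera gave adjusted p-values of 1.8e-13, 0.00512, 8.2e-06 and 1.2e-08 for these 4 lists, in that order. Cd68 rose from 9.92 ± 0.434 to 504 ± 77.8 FPKM, Trem2 by 5.77, and the cholesterol exporters Abcg1 and Abca1 by 5.35 and 3.32. The osteoclast-like list rose (6 of 10 genes, fry adjusted p = 0.00682), with the proton pump subunits Atp6v0d2 (7.16) and Tcirg1 (2.89) and the phosphatase Acp5 (3.93). Outside the naming rule, its members Nfatc1 (0.19), Mmp9 (0.49), Tnfrsf11a (-0.41) and Itgb3 (-0.84) were not called. Dcstamp, Ocstamp, Calcr and Oscar, also on the list, were too low to be tested. Matrix proteases rose (14 of 21, with 2 lower, fry adjusted p = 0.0138), led by Mmp12 at 7.25 and Adam8 at 5.62. Of 24 inflammatory cytokine and adhesion genes, 18 rose and none fell (fry adjusted p = 0.0144), including Ccl3 (5.02), Ccl4 (4.14) and Cxcl16 (3.10). Adjusted over the list alone, 23 macrophage, 7 osteoclast-like, 15 protease and 22 inflammatory genes rose.

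Bone, cartilage and mineralisation lists were not called, except that the mineralisation list passed without CKD 1 or CKD 2 (fry adjusted p = 0.0490, against 0.444 to 0.764 without each other library). Of 11 bone matrix genes, 2 rose and 4 fell (fry adjusted p = 0.965, direction down, with a median of -0.33 and a mean of 0.12), with Spp1 higher and Sost, Sparc and Phex lower. The other rise, outside the naming rule, was Runx2 (log2 fold change 0.89), at 0.36 and 0.28 FPKM in Ctrl and 1.60 and 1.29 in ApoE. Of 11 chondrocyte genes, 2 rose and 4 fell (fry adjusted p = 0.548). Col2a1, the main collagen of cartilage, rose by 2.79 from a mean below 1 FPKM, whereas Cytl1 fell by 1.88. Of 15 mineralisation regulators, 5 rose and 3 fell (fry adjusted p = 0.279, direction up, with a median of -0.09 and a mean of 0.65). Tnfrsf11b, the decoy receptor osteoprotegerin, rose by 2.04 and the phosphate transporter Slc20a2 fell by 1.33. The counts adjusted over the list alone were the same for these 3 lists.

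The clock list fell (11 of 16 lower, 2 higher, fry adjusted p = 0.00521), with Per2 from 65.3 ± 0.510 to 7.12 ± 0.593 FPKM. For this list and for the senescence, postnatal growth, skeletal muscle, phosphate and Schwann cell lists, camera gave an adjusted p of 0.598 with an estimated correlation. With the preset correlation camera called the clock list (adjusted p = 0.00512) and the senescence list (0.0153). It did not call the postnatal growth (0.240), skeletal muscle (0.116), phosphate (0.468) or Schwann cell list (0.237). The senescence list rose (8 of 14, with 2 lower, fry adjusted p = 0.00682), including Gdf15 (3.83) and Cdkn2a (2.46). The postnatal growth list fell (5 of 9, with 1 higher, fry adjusted p = 0.0137), with the glypican Gpc3 at -2.57. Fry also called the skeletal muscle list (4 of 8 lower, adjusted p = 0.0164), the phosphate and kidney hormone list (6 of 14 lower and 3 higher, adjusted p = 0.0300) and the Schwann cell and neuron list (4 of 9 higher and 2 lower, adjusted p = 0.0302). The Schwann cell list lost its call with any of the 6 libraries left out (adjusted p = 0.0806 to 0.252). Among the phosphate and kidney hormone members that fell were Zbtb16, Fkbp5 and Tsc22d3, which are known to respond to glucocorticoids, and Fgfr1. Adjusted over the list alone, the counts differed for the skeletal muscle list (6 lower, 1 higher) and were the same for the other 5. Of 20 white adipocyte genes 14 rose and 1, Plin4, fell (18 and 1 adjusted over the list alone, fry adjusted p = 0.137), with 2 higher without Ctrl 1, ApoE 1 or ApoE 2. Of 13 mitochondrially encoded genes 12 rose (12 adjusted over the list alone, fry adjusted p = 0.0764). That list passed without CKD 1 or CKD 2 (0.0490), whereas without each other library 1 or 2 genes were higher (adjusted p = 0.189 to 0.279). With adipocyte level as a covariate, 0 mitochondrially encoded genes were called by limma, and their median went from 1.54 to 0.48. None of the 22 ribosomal protein genes was called, and the sign of their median depended on the scaling.

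In all, limma called 6208 of 14074 genes, 2781 higher and 3427 lower, of which 3133 changed by at least 1 on the log2 scale. The split was 3112 higher and 3152 lower with median-ratio scaling, 2502 and 3916 with scaling that leaves out mitochondrial and the 50 most abundant genes, and 924 and 873 with adipocyte level as a covariate. The gene count was 3021 without Ctrl 1, 3324 without Ctrl 2, 3582 without ApoE 2 and 1797 with adipocyte level as a covariate, chosen after seeing the data. Fry called 0 lists without Ctrl 1 or Ctrl 2, 6 without ApoE 1 or ApoE 2, 14 without CKD 1 or CKD 2, and 6 with the covariate, under which the contractile list missed the threshold (adjusted p = 0.0757) with 17 genes lower and a median of -2.65, and the osteoclast-like, skeletal muscle, Schwann cell, postnatal growth, senescence and phosphate lists missed it too.

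The second comparison asked how the aorta with medial calcification differed from the young wild-type aorta. Spp1 rose again, from 0.518 ± 0.0616 to 41.7 ± 25.9 FPKM (log2 fold change 4.67, SE 0.41, adjusted p = 0.0145). Upk3b (4.08) and Msln (3.90), both markers of mesothelium, followed, with Hp, Igfbp3, Dgat1, Myl7 and Cxcl13 at 3.68 to 2.98. The largest falls ran from -3.15 for Angptl7 to -2.08 for Map3k7cl, with Casq1, Nrep, Haus8, Mir196a-1 and C1qtnf3 between them, followed by Klk10. None of the 65 called genes named for this comparison kept its call with each of the 6 libraries left out in turn. That outcome was fixed, because no gene at all was called without Ctrl 1 or Ctrl 2.

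Of 26 macrophage genes, 12 rose and none fell, and 20 rose when adjusted over the list alone (median 1.34, fry adjusted p = 0.0584). Cd14 rose by 2.12, Lgals3 by 1.88 and Plin2 by 1.73. Of 7 mast cell genes, 5 rose (6 adjusted over the list alone, fry adjusted p = 0.0281), including Hdc, which makes histamine, at 1.88 and the chymase Cma1 at 1.15. Of 14 phosphate and kidney hormone genes, 5 rose (6 adjusted over the list alone, fry adjusted p = 0.0281), among them Agt (2.91), Ren1 (1.94), Sgk1 (1.53) and the vitamin D receptor Vdr (1.01). Of 14 senescence genes, 3 rose (8 adjusted over the list alone, fry adjusted p = 0.0281), namely Igfbp3 (3.48), Cdkn1a (2.09) and Cdkn2b (1.22). Of 7 cardiomyocyte genes, 3 rose (3 adjusted over the list alone, fry adjusted p = 0.0281): Myl7, Myh6 and Tnnt2, all sarcomere genes of heart muscle. With an estimated correlation camera called none of these 4 lists (adjusted p = 0.416 for each), nor any other list. With the preset correlation it gave adjusted p-values of 2.7e-05 for mast cell, 0.00028 for phosphate and kidney hormone, and 0.00062 for both senescence and cardiomyocyte genes.

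Of 21 contractile genes, 3 fell (13 adjusted over the list alone), with a median of -0.79 (fry adjusted p = 0.168). Des changed by -1.19, Tpm1 by -0.95 and Synpo2 by -0.78. Of 28 matrix genes, 3 fell (9 adjusted over the list alone), with Col1a1 from 416 ± 35.0 to 115 ± 48.3 FPKM and a median of -0.42 (fry adjusted p = 0.302). Of 20 white adipocyte genes, 1 rose (14 adjusted over the list alone, median 2.34, fry adjusted p = 0.330). That gene, Plin1, the coat protein of fat droplets, stood at 8.23 and 17.4 FPKM in the Ctrl libraries and at 135 and 53.0 in the CKD libraries. With adipocyte level as a covariate the medians were -0.31 for contractile, -0.06 for matrix and 0.29 for white adipocyte genes. The white adipocyte genes make up that covariate, so their value is set by construction. None of the 23 oxidative phosphorylation genes was called (median 0.91, and -0.02 with adipocyte level as a covariate, fry adjusted p = 0.302), with Atp5b at 144 and 171 FPKM in Ctrl and 421 and 232 in CKD. None of the 9 MHC class II genes was called either (median -1.06, fry adjusted p = 0.302), with Cd74 at 231 and 233 FPKM in Ctrl and 72.3 and 175 in CKD. None of the 24 inflammatory genes was called (fry adjusted p = 0.661). The counts of these 3 lists adjusted over the list alone were 0 as well. How many contractile, matrix, white adipocyte and oxidative phosphorylation genes were called depended strongly on which library was left out.

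In all, limma called 766 of 14074 genes, 314 higher and 452 lower, of which 419 changed by at least 1 on the log2 scale, and 4217 genes had an unadjusted p below 0.05. The count was 0 without Ctrl 1 or Ctrl 2 (2097 and 2560 genes at an unadjusted p below 0.05), 1 without ApoE 1 or ApoE 2, 38 without CKD 1 (25 higher, 13 lower) and 2416 without CKD 2 (1204 and 1212). It was 1 without the filter, 1 with only the 4 libraries compared and 0 with adipocyte level as a covariate (1474 at an unadjusted p below 0.05), and fry called 2 lists without CKD 1, macrophage and cardiomyocyte, and 0 without any other library.

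**Figure D2:**
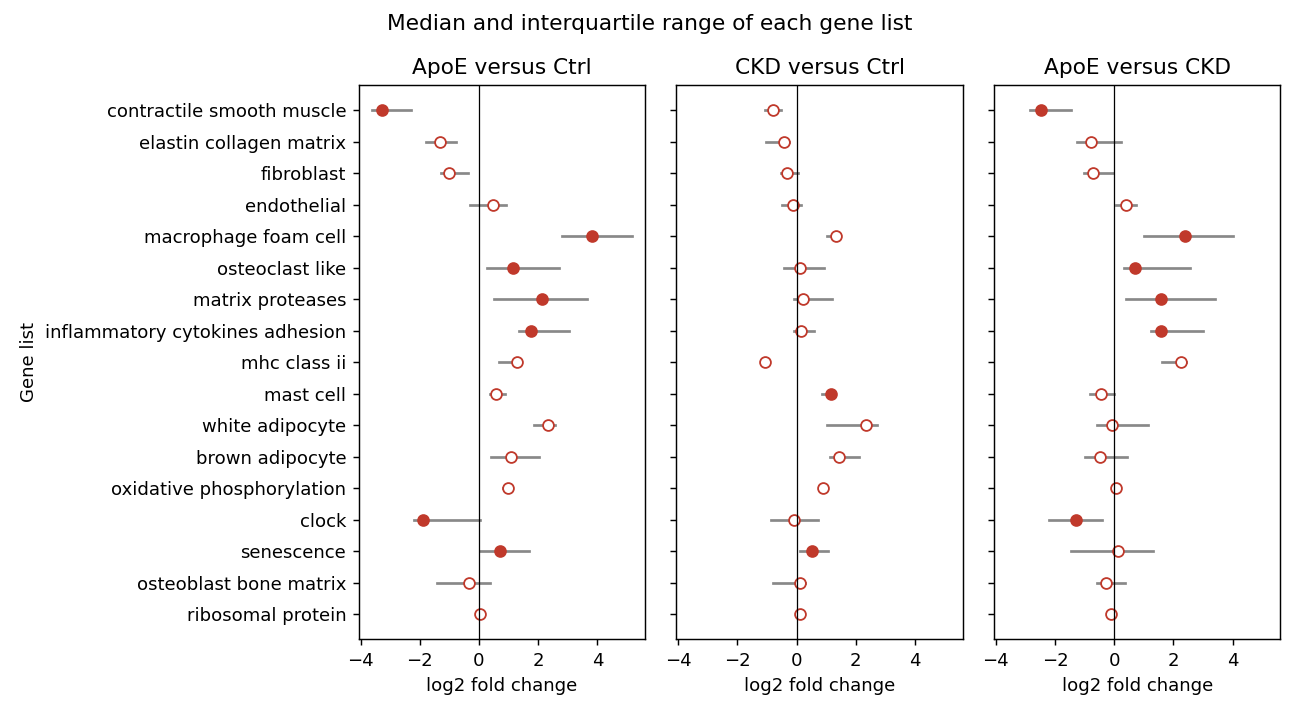
Median log2 fold change of 17 gene lists (points) with the interquartile range over genes (lines) in the 3 comparisons; filled points are lists called by fry. The contractile list lay at -3.27 in ApoE versus Ctrl, -0.79 in CKD versus Ctrl and -2.47 in ApoE versus CKD.

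The third comparison set both models against each other. Macrophage genes were higher and contractile genes lower in ApoE than in CKD. Among the largest differences were Cd5l (10.02), Spp1 (6.22), Atp6v0d2 (5.99), Gpnmb (5.83), Mpeg1 (4.79), Abcg1 (4.67), Clec7a (4.52) and Fabp5 (4.44) on the higher side, and Apoe (-6.75), Mir143 (-5.60), Mir145a (-5.09), Carmn (-4.92), Sost (-4.33), Xirp1 (-4.10) and Zbtb16 (-4.08) on the lower side. Of 21 contractile genes, 20 were lower (fry adjusted p = 0.00926), and of 26 macrophage genes, 19 were higher and 1 lower (fry adjusted p = 0.00876). With an estimated correlation camera gave an adjusted p of 0.673 and 0.621 for these lists, and of 0.621 to 0.735 for the osteoclast-like, protease and inflammatory lists. With the preset correlation camera gave adjusted p-values of 4.1e-10, 1.4e-09, 0.00359, 4.4e-05 and 8.0e-08 for the same lists, in that order. Osteoclast-like genes (5 of 10, fry adjusted p = 0.00926), matrix proteases (12 of 21, with 2 lower) and inflammatory genes (18 of 24, and 10 without ApoE 1) were higher in ApoE, each with a fry adjusted p of at most 0.0202. Adjusted over the list alone, 21 contractile genes were lower, and 19 macrophage, 5 osteoclast-like, 13 protease and 21 inflammatory genes were higher.

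Of 9 MHC class II genes, 8 were higher in ApoE and none lower (9 adjusted over the list alone, fry adjusted p = 0.0671), and 1 was without ApoE 2, with Cd74 at 2.52. Clock genes (11 of 16, with 1 higher), phosphate and kidney hormone genes (8 of 14) and cardiomyocyte genes (5 of 7) were lower in ApoE, each with a fry adjusted p of 0.00876. With an estimated correlation the camera adjusted p was 0.546, 0.546 and 0.621 for these lists and 0.735 for the postnatal growth list. With the preset correlation the camera adjusted p was 0.00021, 0.00074 and 0.0107 for these lists and 0.150 for the postnatal growth list. Of the clock, phosphate and cardiomyocyte genes, Ciart changed by -3.00, Per1 by -2.58, Fkbp5 by -2.97 and Tnnt2 by -2.24. The postnatal growth list was lower too (4 of 9, with 1 higher, fry adjusted p = 0.00926). Adjusted over the list alone, 12 clock, 8 phosphate and kidney hormone, 5 cardiomyocyte and 5 postnatal growth genes were lower. Of 20 white adipocyte genes, 3 were higher and 1 lower (0 and 1 adjusted over the list alone, fry adjusted p = 0.950, direction down, with a median of -0.09 and a mean of 0.21).

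In all, limma called 5592 of 14074 genes, 2608 higher in ApoE and 2984 lower, of which 2550 differed by at least 1 on the log2 scale. The split was 2887 higher and 2873 lower with median-ratio scaling, and the count was 2914 without ApoE 2 (1611 and 1303). Fry called 0 lists without Ctrl 1, Ctrl 2 or ApoE 2, 4 without ApoE 1, and 14 with adipocyte level as a covariate.

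The overlap of both models against the same controls was then counted. Of the genes called in CKD versus Ctrl, 185 were higher in both models, where 62.0 would be shared by independent lists, and 334 were lower in both, where 110 would be. The 5 genes that the rule names among those called in the same direction were Spp1, Mmp12, Lgals3, Angptl7 and Adam8; Angptl7 fell by 4.62 in ApoE and by 3.15 in CKD. A further 22 genes moved in opposite directions. Metallothionein Mt1 changed by -1.60 in ApoE and 1.61 in CKD, Itga5 by -2.02 and 0.89, Map3k6 by -1.99 and 1.08, and Myoc by -1.32 and 1.56, beside Apoe itself. Across genes, which are not independent replicates, the log2 fold changes had r = 0.495. Unchanged groups simulated with shared controls gave 0.497. Equal group sizes largely set that value for unchanged groups, whose fold changes hold only noise. The observed fold changes had SDs of 1.056 in ApoE and 0.563 in CKD. The value of 0.497 is therefore no reference for the observed r, and their match does not tell a shared response from shared controls. The simulation was corrected, after its first result was seen, to redraw the controls, and the version with fixed controls had given a much lower correlation. The covariance was 0.294 against 0.0235 in the simulation, a difference of 0.271. In the 100 simulations at most 3 genes were called in both. Unchanged groups yield almost no calls, so that count had to be small and is no reference for the observed overlap. The controls could not be split, with 2 libraries, and part of the excess in covariance and overlap may come from them. Adipocyte level differs between Ctrl and both models, so as a covariate it removes part of their difference from Ctrl. In ApoE versus CKD limma called 5979 genes with it and 5592 without it. A loss of overlap with this covariate therefore does not show that fat explains the overlap. The overlap of 519 genes in the same direction became 0 with adipocyte level as a covariate and 0 without Ctrl 1 or Ctrl 2, 1 without ApoE 1 or ApoE 2, 34 without CKD 1 and 1588 without CKD 2.

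**Figure D3:**
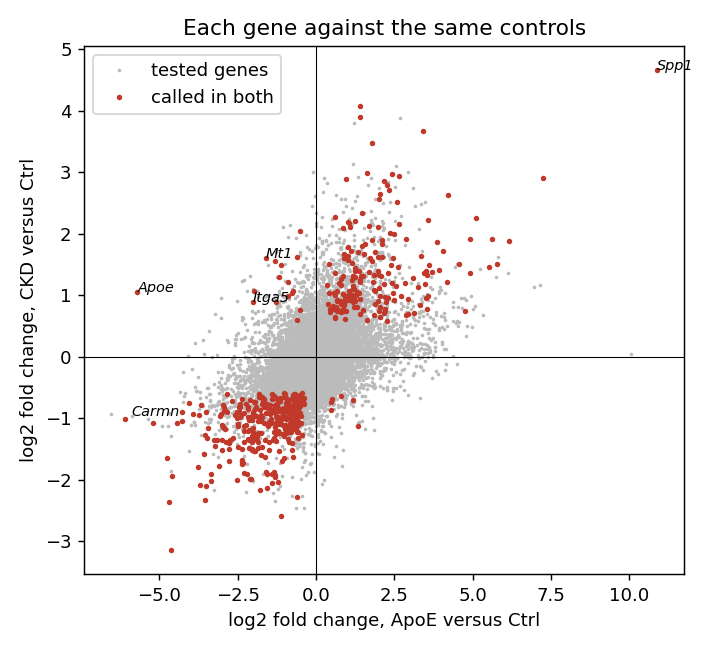
Log2 fold change of each of 14074 genes in ApoE versus Ctrl (horizontal) and CKD versus Ctrl (vertical), with genes called in both in red. Of these, 185 lie in the upper right and 334 in the lower left, and 22 lie in the other quadrants.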

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

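With 2 libraries per group, calls rest on a spread shared by all 3 groups. A lone library was taken to vary like the others. The fit on recovered reads and the adipocyte covariate were chosen after seeing the data. Planned count models were not run, as values are FPKM. For genes called in ApoE versus Ctrl the count was 3133 with an absolute log2 fold change of at least 1 and 1797 with the adipocyte covariate, and 3021 to 7019 with each library left out. For ApoE versus CKD it was 2550 with the fold-change minimum and 2914 to 5045 with each library left out. For CKD versus Ctrl it was 419 with the fold-change minimum, 1 without a filter, 1 with only the 4 libraries compared, 0 with the adipocyte covariate, and 0 to 2416 with each library left out. These counts are from limma. Unadjusted p was below 0.05 for 5269, 3903 and 1474 genes without a filter, with 4 libraries and with the covariate. Apart from the replicate block, the other alternatives, among them median-ratio and upper-quartile scaling, pseudocount 0.1 and voom on recovered reads (5489, 956 and 4854 genes), stayed within 1.5 times. The covariate takes 1 of 3 residual degrees of freedom and differs by group, so its losses need not mean fat. Causes of other losses were untested.

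The overlap was 233 genes with the fold-change minimum, 0 with the adipocyte covariate and 0 to 1588 with each library left out. Lists called by camera with a preset correlation numbered 20, 18 and 15 in ApoE versus Ctrl, CKD versus Ctrl and ApoE versus CKD, and 0 in each with an estimated one. With upper-quartile scaling fry called 13, 4 and 11 lists, gaining matrix and mast cell in ApoE versus Ctrl and senescence and endoplasmic reticulum stress in ApoE versus CKD. With the adipocyte covariate fry called 6, 0 and 14 lists, gaining endothelial and endoplasmic reticulum stress in ApoE versus Ctrl, and these, both adipocyte lists and the BMP, TGF-beta and Wnt list in ApoE versus CKD. The white adipocyte list makes up the covariate, so its own call there carries no information. The ApoE versus Ctrl lists that lost the call (adjusted p = 0.0757 to 0.221) had medians of -2.65 for contractile (-3.27 without the covariate), 1.05 for osteoclast-like (1.14), -1.03 for skeletal muscle (-0.77), 0.68 for Schwann cell (0.19), -0.40 for postnatal growth (-0.41), 0.58 for senescence (0.73) and -0.37 for phosphate and kidney hormone (-0.09). The CKD versus Ctrl lists that lost the call (adjusted p = 0.189 each) had medians of 1.03 for mast cell (1.15 without the covariate), 0.53 for phosphate and kidney hormone (0.53), 0.77 for senescence (0.53) and 1.32 for cardiomyocyte (0.66). Fry called 0 lists in CKD versus Ctrl without a filter. With each library left out it called 0 to 14, 0 to 2 and 0 to 9. Without CKD 1 or CKD 2 it gained the matrix, mineralisation, oxidative phosphorylation and mitochondrially encoded lists in ApoE versus Ctrl and lost the Schwann cell list.

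The replicate numbers are shared only as numbers. With the replicate number as a block, CKD versus Ctrl had 46 genes called, the overlap held 33 genes, and fry called 0 lists in CKD versus Ctrl and 1, the clock list, in ApoE versus CKD. In ApoE versus Ctrl it lost the protease, inflammatory and phosphate lists (adjusted p = 0.0604 to 0.0964). Deviations of same-numbered libraries correlated across genes at 0.046 (Ctrl and ApoE), -0.233 (Ctrl and CKD) and -0.097 (ApoE and CKD).

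Named genes were refitted under median-ratio and upper-quartile scaling, without a filter, with the replicate block and with each library left out, and not under the other alternatives. No called named gene changed direction under these. Of 157, 65 and 142 called named genes in the 3 comparisons, 111, 0 and 101 kept the call with each library left out. Of the named genes, only check genes without a call changed sign under these. Under median-ratio scaling Uty was at 0.02 in ApoE versus Ctrl and Kdm5d at 0.00 in CKD versus Ctrl. With each library left out, Uty spanned -0.13 to 0.07 in ApoE versus Ctrl, -0.20 to 0.09 in CKD versus Ctrl and -0.12 to 0.17 in ApoE versus CKD. Kdm5d spanned -0.12 to 0.08 and Wdfy1 0.00 to 0.09 in CKD versus Ctrl. In ApoE versus CKD, Apoc1 spanned -1.33 to 0.19, Tomm40 -0.13 to 0.33 and Clptm1 -0.02 to 0.02.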

Other observations

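The tests of adipocyte genes as a block, of a uniform loss of smooth muscle, of age and of the adipocyte covariate, and voom on recovered reads, were chosen after the results were seen. Members of further gene groups were called in ApoE versus Ctrl, although fry called none of the lists without a covariate. With adipocyte level as a covariate it called the endothelial and endoplasmic reticulum stress lists (adjusted p = 0.0447 for each, with 3 genes higher in each and medians of 0.48 and 0.70). Of 18 endothelial genes, 7 rose and 2 fell (fry adjusted p = 0.137), with Emcn at 1.49. Of 16 cell cycle genes, 8 rose and none fell (fry adjusted p = 0.137), with Cdk1 at 1.15. Of 19 interferon response genes, 10 rose and none fell (fry adjusted p = 0.112), with Oas1a at 2.67. In CKD versus Ctrl, 3 interferon response genes fell (fry adjusted p = 0.589): Igtp (-1.74), Iigp1 (-1.45) and Gbp2 (-1.01). Of 22 BMP, TGF-beta and Wnt genes, 12 fell and 3 rose in ApoE versus Ctrl (fry adjusted p = 0.127), with Wnt16 at -2.09 and Grem1, a BMP antagonist, at 2.95. Of 17 endoplasmic reticulum stress genes, 6 rose and 1 fell (fry adjusted p = 0.0780), with Sdf2l1 at 2.75. With calls adjusted over the list alone, 7 endothelial, 9 cell cycle, 10 interferon response and 7 endoplasmic reticulum stress genes rose and 12 BMP, TGF-beta and Wnt genes fell. Over all genes tested, without Ctrl 1 the endothelial, cell cycle, interferon response and endoplasmic reticulum stress lists had 1, 0, 3 and 2 genes higher, and without ApoE 1 they had 2, 0, 6 and 2. The BMP, TGF-beta and Wnt list had 6 lower without ApoE 2. In CKD versus Ctrl, 4 of 16 clock genes fell and 1, Nfil3, rose (5 and 5 adjusted over the list alone, fry adjusted p = 0.277, direction down), with Hlf at -1.24, and the median was -0.10, and 0.45 by voom on recovered reads. Of 21 matrix proteases, 3 rose (5 adjusted over the list alone, fry adjusted p = 0.302), with Mmp12 at 2.91, and of 14 brown adipocyte genes 1, Ppargc1a, rose (6 adjusted over the list alone, fry adjusted p = 0.168).

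Unlike the macrophage, osteoclast-like and inflammatory lists, the following immune lists were not called in ApoE versus Ctrl, apart from the mast cell list under upper-quartile scaling (fry adjusted p = 0.0470). Of 12 B and plasma cell genes, 6 rose and none fell (fry adjusted p = 0.163), with Cd22 at 2.95. Of 7 mast cell genes, 4 rose (fry adjusted p = 0.0540), of 13 complement genes 5 rose and 1 fell (fry adjusted p = 0.163), of 9 neutrophil genes 3 rose (fry adjusted p = 0.184) and of 14 T cell genes 1, Il7r, rose (fry adjusted p = 0.714, direction up). The T cell median of -0.04 changed sign with the scaling, and it was -0.88 without Ctrl 1, with 6 genes lower, and 0.80 without Ctrl 2. Cd8a, chosen after its values were seen, stood at 0.611 FPKM in Ctrl 1 and 9.66 in Ctrl 2. MHC class II genes (2 of 9 higher, fry adjusted p = 0.177) and lymphoid chemokine genes (2 of 7 higher, fry adjusted p = 0.137) were not called. Of metabolic lists, none of which fry called with all 6 libraries, 16 of 23 oxidative phosphorylation genes rose (fry adjusted p = 0.140), 9 of 20 fatty acid oxidation genes (fry adjusted p = 0.140), 4 of 14 brown adipocyte genes, with 1 lower (fry adjusted p = 0.365), and 5 of 17 cholesterol genes, with 2 lower (fry adjusted p = 0.163). The oxidative phosphorylation list passed without CKD 1 or CKD 2 (0.0490, with 21 genes higher), whereas without each other library 0 to 2 were higher (adjusted p = 0.273 to 0.437), and fatty acid oxidation genes numbered 0 without Ctrl 1, ApoE 1 or ApoE 2. With adipocyte level as a covariate limma called 0 oxidative phosphorylation and 0 fatty acid oxidation genes, and the medians went from 0.99 to 0.03 and from 1.15 to -0.19. Of 16 immediate early genes, 6 fell and 1 rose (fry adjusted p = 0.0840), of 7 cardiomyocyte genes 2 rose and 2 fell (fry adjusted p = 0.427, direction down, with a median of 0.12, and -0.42 by voom on recovered reads), and of 5 erythroid genes none was called (fry adjusted p = 0.926). When adjusted over the list alone, 7 B and plasma cell, 19 oxidative phosphorylation and 15 fatty acid oxidation genes rose, 2 immediate early genes rose and 3 cardiomyocyte genes fell, and the other counts were the same. With 1 library left out, B and plasma cell genes called higher numbered 2 to 6, mast cell genes 1 to 4, complement genes 3 to 6, cholesterol genes 2 to 7 and brown adipocyte genes 0 to 6, and immediate early genes called lower 3 to 6.

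In CKD versus Ctrl the white adipocyte list had a median of 2.34, the contractile list -0.79 and the matrix list -0.42, and fry called none of them. Of 34 adipocyte genes, 97.1% were higher both in CKD 1 than CKD 2 and in Ctrl 2 than Ctrl 1. They thus moved as a block within groups, which may reflect how much fat was taken with each aorta. Between CKD and Ctrl they moved less evenly, with white adipocyte quartiles of 1.03 and 2.72. Adipoq changed by 3.10, whereas Scd1 changed by 0.05 and Fasn by -0.02. A single amount of fat was thus not shown to set them all. The median of the matrix list lay 0.37 above that of the contractile list (SE 0.15 over genes), as dilution of the vessel wall by other tissue would allow. The lower quartiles were close, at -1.022 for matrix and -1.065 for contractile genes. The largest matrix falls, Col1a1 and Col3a1 at -1.91 each, went beyond the largest contractile falls, Itga8 and Pgm5 at -1.29 each. Dilution by 1 factor was thus not shown for these collagens. With the adipocyte level as a covariate limma called no gene, 1474 had an unadjusted p below 0.05, and the medians were 0.29 for white adipocyte, -0.31 for contractile, -0.06 for matrix and 1.73 for macrophage genes (1.34 without it). The white adipocyte value is set by construction, since that list makes up the covariate. The covariate also differs between the groups, so these values cannot tell fat from an effect of group. An effect of kidney failure on fat or matrix remains open and was not tested.

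In ApoE versus Ctrl the contractile list fell far. Dilution by cells without endothelial transcripts would lower endothelial genes as well. The contractile list lay -3.75 (SE 0.42 over genes) from the endothelial list, which argues against such dilution as the whole cause. White adipocyte genes rose as well (14 of 20), and of 18 endothelial genes 7 rose and 2 fell. Added tissue that brings endothelial transcripts would escape this test, so dilution by it was not excluded. A uniform loss of smooth muscle cells would lower all contractile genes by one factor, but their interquartile range was 1.32, and 1.39 without the pseudocount. Age remains open: the median in ApoE versus CKD was -2.47, but the age of the CKD mice is in doubt, so age and genotype cannot be told apart. Wdfy1, a substrain check, was lower in ApoE than in Ctrl and CKD, so strain background may differ too, which was not tested. A change of smooth muscle state with plaque formation was not tested.

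Genes near Apoe could differ through a chromosome 7 segment carried over from the cells used to make the knockout. Leaving out Apoe, 58 of 210 tested genes within 10 Mb were called the same way against Ctrl and CKD, and 255 of 841 further away (27.6% and 30.3%; Fisher's exact test, 1-sided, p = 0.802). The odds ratio of 0.877 had a 95% interval of 0.615 to 1.24, which reaches above 1, so a carried-over segment that alters a few genes cannot be told apart from none. The neighbours Bcam and Nectin2 changed by -2.96 and 1.52 in ApoE versus Ctrl.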
